A study of Homo sapiens with 4 samples.

How the data were processed

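Gene expression was measured on 4 single-colour arrays, 1 for each combination of cell line and treatment. The lines were HOS and U2-OS, 2 established human osteosarcoma lines, and the treatment was OGE at 0 or 600 μg/mL for 24 h. The labels do not spell out what OGE stands for. Per the labels' protocols, total RNA was extracted with Trizol, amplified, labelled with biotin by a whole-transcript sense-strand method and hybridised, 1 sample to an array.

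The deposited values are on a log2 scale and were made by RMA, per the submitters' processing notes, which give no version. RMA corrects background, brings the arrays to a common distribution and summarises the probes of a probe set. The log base is not written in the file and was taken from the range of the values, which lay between 0.16 and 13.41. Values carry 2 decimals, so a difference of 0.01 is the smallest step. RMA pulls low signals together and assumes that most genes do not shift in one direction, so changes of low genes are understated and a shift of all genes would not be seen.

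The table holds 33297 probe sets. The platform annotation used, of 2016, gives 1 gene symbol for 19460 of them, several symbols for 1754 and none for 12083. Of the probe sets with 1 symbol, 19429 were matched by gene ID to the RefSeq gene table of GRCh38.p14 and 31 kept the annotation's symbol. This left 18417 genes. For the 769 genes with more than 1 probe set, the one with the highest mean over the arrays was used. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. Gene spans and the genes that contain a small nucleolar RNA were taken from the RefSeq table.

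With 1 array per group there is no replicate within a line, and no p-value was computed there. A gene was called higher or lower by size when the log2 difference between the arrays was at least 1, which is 2-fold, and the higher value was at or above that array's median over all probe sets. Differences between the lines were called by size when they passed this rule with the same sign in both treatment states. The test across genes was limma, with cell line and OGE as terms, on all 18417 genes. It treats the lines as the repeats of the OGE contrast and has 1 residual degree of freedom before its moderation. Adjusted p-values are Benjamini-Hochberg with a threshold of 0.05. Nothing in the labels says that the arrays came from separate cultures, so these p-values measure only the spread between these arrays. No scan date or batch is given in the sources used here.

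Before the data were examined, 35 gene lists were fixed. For a list with at least 3 members at or above the median mean level, the median change of those members was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5. This describes these arrays and is not a test across cultures. Members of a list were also tested with limma adjusted over the list alone. That adjustment takes no account of the number of lists, so its counts do not hold over all genes. The difference of the 2 responses within a list was placed among random lists in the same way, a measure chosen after the list results had been seen.

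Genes are named by a rule fixed before the data were examined. It takes the 10 largest rises and falls by size in each line, the 10 in each direction with the largest smaller change among genes called in both lines, up to 5 of each kind called in opposite directions, and the 10 in each direction by the smaller of the differences between the lines. Of each list described, it takes up to 4 members with the largest change. Symbols that start with LOC, SNORD, SNORA, RNU or MIR, olfactory receptors, genes named after open reading frames, XIST and Y-linked genes were left out of the first parts of the rule.

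Both steps were tested on simulated data. With changed genes added to simulated arrays, limma recovered 0% of 100 genes with a log2 change of 1 and 0% of 100 with a change of 2 in the OGE contrast over 18417 genes. The size threshold in both lines, applied there without the floor, called 27% and 98% of them, and 59 of 18217 unchanged genes. The simulated noise was drawn from limma's fit to the values as deposited, whose moderation had 3.55 prior degrees of freedom. With uniform noise within the rounding step these were 5.43, and after quantile normalization 7.14. The fitted spread also includes any difference between the lines' responses, so the recovery and the 59 apply to that noise only. Of simulated lists of 20 genes in U2-OS, 2.5% stood apart with no shift and 96.5% with a shift of 0.5.

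Alternatives were other size thresholds, no floor or a floor at the 75th percentile of the array, quantile normalization, cyclic loess, the mean of a gene's probe sets, limma with a trend and robust moderation, limma without the block, limma on the genes at or above the median level, and all measured members of a list. Added after the data were seen was limma on values with uniform noise within the rounding step, since rounding gave some genes exactly equal changes in the lines. One of the fixed lists, with a check planned on it before its result, is not reported here, though the counts of lists that stood apart include it. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.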

Results

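Expression was profiled in HOS and U2-OS osteosarcoma cells, each with and without 600 μg/mL OGE for 24 h, on 1 array per condition. The series addresses how OGE affects gene expression in these lines. Array medians lay between 3.58 and 3.62 on the log2 scale, and no arrays were identical. Over all probe sets, the control and OGE arrays correlated at 0.980 in HOS and 0.968 in U2-OS. The number of arrays limits the precision of every value, and there were no replicates within a line.

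In HOS, the lists of ATF4 and NRF2 targets lay above random lists with OGE, and those of mitosis and matrix genes below them. SMOX, an enzyme that oxidises spermine, was higher by 2.98 (log2), the glucose transporter SLC2A3 by 2.59, the phosphatase subunit PPP1R15A by 2.53 and the arrestin-related ARRDC3 by 2.46. The cystine transporter SLC7A11 was higher by 2.26, the autophagy receptor SQSTM1 by 2.15 and the stress gene GADD45G by 2.13. SCARNA9L, AMZ2P1 and SCARNA7 were higher by 2.54, 2.44 and 2.17. With the mean of its probe sets, SCARNA9L was higher by 1.43. MAMDC2 had a change of -2.64, SKP2, a subunit of a ubiquitin ligase that degrades cell cycle inhibitors, of -2.06, and TENM2 of -2.01. ATP8B1, the fatty acid elongase ELOVL2 and the fibrillin FBN2 each had a change of -1.87, and PRSS23, the myosin MYH10, PLAC8 and PAGE2B had changes from -1.77 to -1.68. By size, 193 genes were higher and 247 lower, 3.88% of the 11334 genes at the floor.

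In U2-OS, the lists of hypoxia genes and ATF4 targets lay above random lists with OGE, and those of mitosis and matrix genes below them. MMP3, a matrix metalloproteinase, was at 2.64 without OGE and 9.71 with it, a change of 7.07, against 0.50 in HOS. GDF15, a stress-induced cytokine, was higher by 5.22, DDIT4, an inhibitor of mTORC1 signalling, by 4.89, the peptide hormone ADM by 4.76, the glycolytic enzyme HK2 by 4.41 and the heme oxygenase HMOX1 by 4.19. UPP1, PPP1R15A, DEPP1 and the lipid droplet gene PLIN2 were higher by 3.72, 3.59, 3.36 and 3.32. Lower were the dopamine receptor DRD1 with -3.42, LRRN1 with -3.34, SLC2A12 with -2.85, the kinetochore gene SKA2 with -2.80 and HAPLN1 with -2.74. TGFB2, PLAC8, LTBP1, ACADM and H2BC12 had changes from -2.56 to -2.47. By size, 338 genes were higher and 907 lower, 10.8% of the 11506 genes at the floor.

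**Figure D1:**
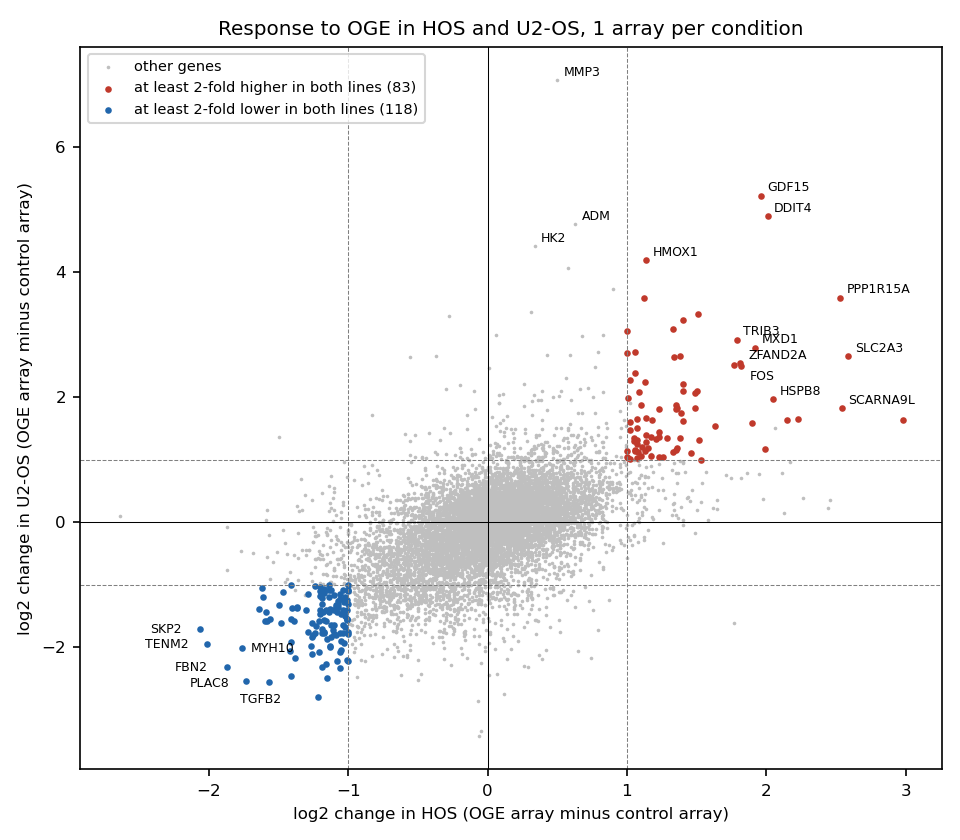
Log2 change with OGE in U2-OS (vertical axis) against HOS (horizontal axis), 1 point per gene with a mean level at or above the median or called in a line; dashed lines mark a change of 1 in either direction. The 83 genes higher and 118 genes lower in both lines lie in opposite corners, and MMP3 has the highest point for U2-OS.

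The responses of the lines shared 201 genes by size, 83 higher and 118 lower, and no gene was called in opposite directions. If the calls were independent, 4.91 higher and 15.96 lower shared genes would be expected among the 10811 genes at the floor in both. On simulated arrays the size threshold alone, without the floor, called 59 of 18217 unchanged genes in both lines, against 209 genes called without the floor here. SLC2A3 was higher by a mean of 2.62 ± 0.05 (SD, n = 2 lines), PPP1R15A by 3.06 ± 0.75, DDIT4 by 3.45 ± 2.04, the small heat shock protein HSPB8 by 2.01 ± 0.06 and GDF15 by 3.59 ± 2.31. MXD1, a MYC network repressor, SCARNA9L, the immediate early gene FOS, ZFAND2A and the pseudokinase TRIB3 were higher by means of 2.35, 2.18, 2.16, 2.18 and 2.35. TENM2 had a mean change of -1.98 ± 0.04, FBN2 of -2.09 ± 0.31, MYH10 of -1.89 ± 0.18, PLAC8 of -2.13 ± 0.57 and SKP2 of -1.88 ± 0.25. HIBCH, RCN2, TGFB2, ANXA1 and FSTL1 had mean changes from -2.07 to -1.54. Across 9209 genes at or above the median level, the changes in the lines correlated at r = 0.574, where genes are not independent replicates.

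Across the lines, limma called 0 genes for OGE, with a smallest adjusted p of 0.228. At an unadjusted p under 0.05 there were 2615 genes, against 921 expected by chance. On simulated data, with noise set from the spread between the lines' responses, limma recovered 0% of genes with log2 changes of 1 or 2. After quantile normalization limma called 272 genes, 98 higher and 174 lower, of which 191 were among the 201 shared by size. The OGE results below therefore rest on size and on the placement of lists among random lists. Where given, limma adjusted over a list alone is a description without correction for the number of lists.

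**Figure D2:**
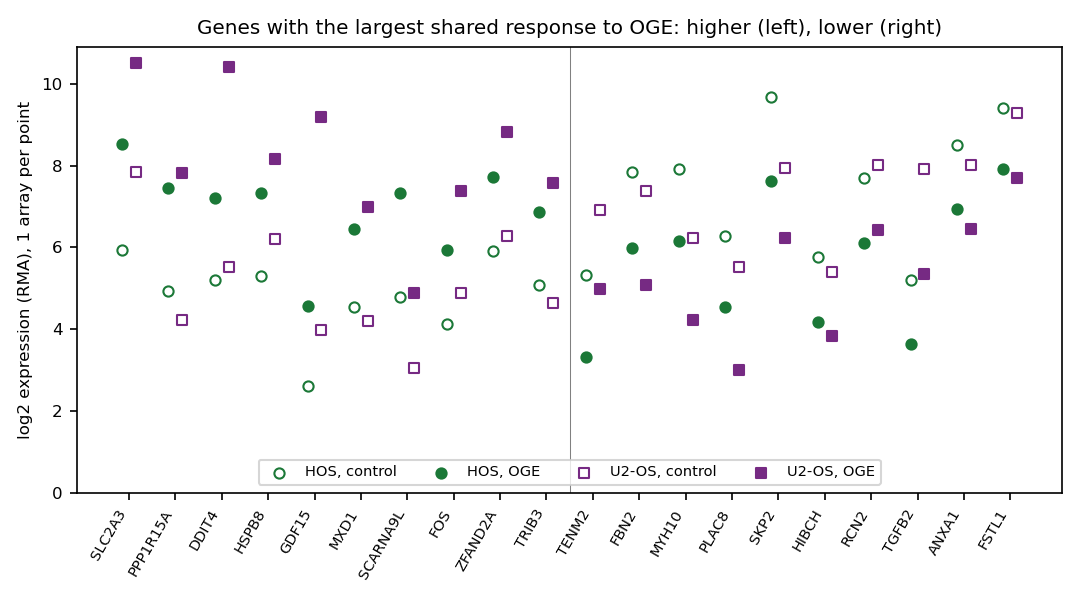
Log2 expression of the 20 genes with the largest shared response, 1 point per array, with HOS as circles, U2-OS as squares, control open and OGE filled. The 10 genes on the left are higher with OGE in both lines and the 10 on the right are lower.

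Genes of mitosis were lower with OGE in both lines. Of 34 measured members, 9 were lower by size in HOS and 19 in U2-OS, 8 of them in both, and none was higher. The list's median change was -0.67 in HOS and -1.35 in U2-OS, each at percentile 0 among random lists. The kinase PBK had changes of -1.06 and -2.07, the spindle checkpoint kinases BUB1 and BUB1B of -1.13 and -1.98 and of -1.05 and -2.04, and DLGAP5 of -0.62 and -2.44. Adjusted over the list alone, limma called 19 members, against 0 over all genes. Genes of G1/S entry and DNA replication had a median of -0.02 in HOS, at percentile 41.8, or 0.01 after quantile normalization, and -0.77 in U2-OS, at percentile 0. SKP2, MCM6, POLE2 and RRM1, 4 members, passed limma adjusted over the list alone. Homologous recombination genes had medians of -0.18 and -1.21, at percentiles 8.12 and 0.01, the first within the range of random lists and -0.05 over all measured members, with 6 of 11 members lower by size in U2-OS, among them BRIP1 with -1.52 and FANCI with -1.31. No member passed limma adjusted over the list alone, where the smallest adjusted p was 0.0875. Among the inhibitors of cyclin-dependent kinases, CDKN1A was higher by 1.02 and 1.47, while CDKN1B had changes of -0.41 and -1.29.

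Matrix genes were lower in both lines, with medians of -0.73 and -1.05, both at percentile 0. The random lists were not matched on gene span, and genes of longer span were lower in both lines, as given below. By size, 7 of 28 members were lower in HOS and 11 in U2-OS, 6 in both, and none was higher. FBN2 had changes of -1.87 and -2.31, COL12A1 of -1.26 and -2.10, COL3A1 of -1.13 and -1.99, and the fibronectin gene FN1 of -1.61 and -1.20. Adjusted over the list alone, limma called 13 members. Fatty acid synthesis genes had medians of -0.52 and -0.80, at percentiles 0.36 and 0.16, with ACACA at -0.67 and -1.16 and ELOVL6 at -1.20 and -0.58, and 6 members passed limma adjusted over the list alone.

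Targets of ATF4 and CHOP, which respond to amino acid shortage and other stress, were higher in both lines. Of 32 measured members, 13 were higher by size in HOS and 13 in U2-OS, 8 in both, and none was lower. Medians were 0.68 and 0.72, both at percentile 100. DDIT4 was higher by 2.01 and 4.89, TRIB3 by 1.79 and 2.92, and CTH, an enzyme of cysteine synthesis, by 1.77 and 2.52. Adjusted over the list alone, limma called 12 members. Endoplasmic reticulum chaperones went the other way, with medians of -0.33 and -0.40 at percentiles 1.74 and 4.31, the second within the range of random lists. HSP90B1 had changes of -0.97 and -1.94 and PDIA6 of -0.98 and -1.02, while HERPUD1 was higher by 0.80 and 1.12.

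Hypoxia and glycolysis genes had medians of 0.55 and 0.73, both at percentile 100, with 6 of 29 members higher by size in HOS, 12 in U2-OS and 5 in both. ADM was higher by 0.63 and 4.76, HK2 by 0.34 and 4.41, and NDRG1 by 1.40 and 3.23. Adjusted over the list alone, limma called 13 members. NRF2 targets, which serve antioxidant defence, had medians of 0.69 and 0.32, at percentiles 100 and 99.6. HMOX1 was higher by 1.14 and 4.19, the ferritin light chain FTL by a mean of 1.74 over the lines, SRXN1 by 1.99 and 1.17 and GCLM by 2.11 and 0.79. Immediate early genes had medians of 0.81 and 0.92, both at percentile 100, with 8 of 27 members higher by size in each line and 5 in both. Over all measured members the U2-OS median was 0.56. FOS was higher by 1.82 and 2.5, MYC by 1.00 and 3.05, ATF3 by 0.68 and 2.98 and DUSP5 by 1.35 and 1.88.

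Small nucleolar RNA genes had medians of 0.50 in HOS and 0.97 in U2-OS, both at percentile 100, over 72 genes at the level. Over all 176 measured members the medians were 0.35 and 0.46, also at percentile 100. By size, 19 of the 176 were higher in HOS and none lower, 40 were higher and 1 lower in U2-OS, and 12 were higher in both. SNORD14E was higher by 1.12 and 3.59 and SNORA5A by 2.23 and 1.65.

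In all, 14 of 33 lists stood apart in HOS and 17 in U2-OS, and 9 stood apart on the same side in both. For lists of unrelated genes 1.65 would be expected in each line. Genes of a list can move together and some lists share members, so that number may be too low and the counts are not a test. Of markers of other cell types, those of epithelium had medians of 0.02 and 0.30 over 3 genes at the level and did not stand apart, and the median in HOS was -0.10 over all measured members. With 2 immune and 1 endothelial markers at the level, those lists were not placed. The immune marker CD68, a lysosomal protein, was higher by 1.05 and 1.35 and passed limma adjusted over the list alone, with an adjusted p of 0.0209.

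**Figure D3:**
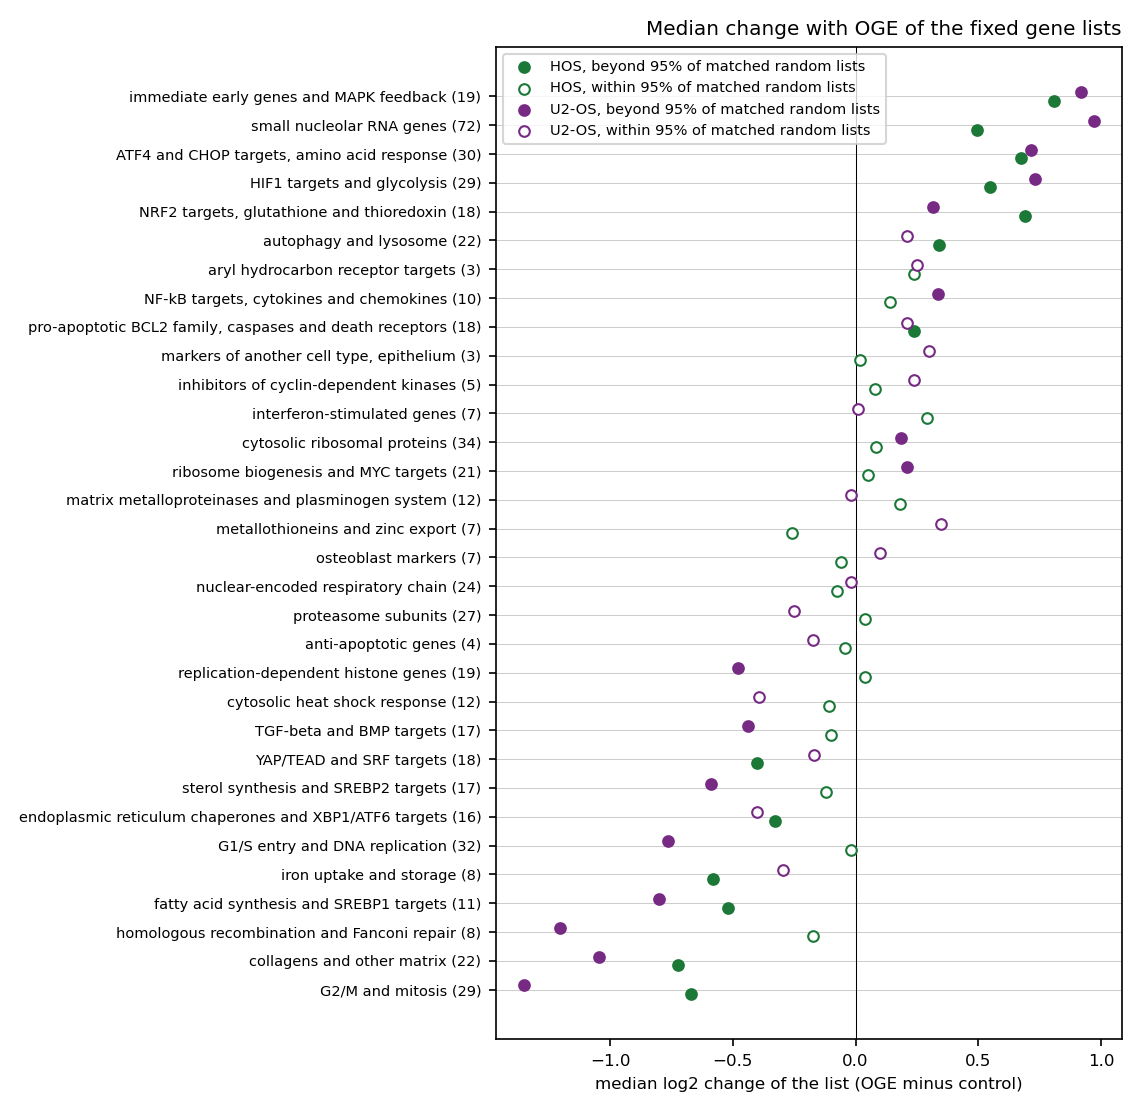
Median log2 change with OGE of the gene lists reported here in HOS (green) and U2-OS (purple), with the number of members at or above the median level in brackets; filled points lie beyond 95% of random lists matched on level. Mitosis and matrix lists lie at the lower end in both lines, and immediate early, small nucleolar RNA, ATF4 and hypoxia lists at the upper end.

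Between the lines, irrespective of OGE, U2-OS had higher levels of CRYAB, IL18 and DHRS2, and HOS of H3C11, UCHL1 and CLDN11. CRYAB, a small heat shock protein, differed by 6.38 without OGE and 5.79 with it, IL18 by 4.91 and 4.84 and the short-chain dehydrogenase DHRS2 by 6.98 and 4.79. MAGEB2 differed by 4.52 and 4.44 and MAGEA4 by 4.01 and 4.15. RFPL4A, TSPYL5, ZNF667-AS1, PCDHB5 and ANKRD1 were also higher in U2-OS, and the smaller of each gene's differences lay between 3.43 and 4.51. H3C11, a histone gene, differed by -5.87 and -5.69, the ubiquitin hydrolase UCHL1 by -4.87 and -5.67, ATP6V0A1 by -4.86 and -5.26 and the tight junction gene CLDN11 by -5.48 and -4.46. FOXR1, the BMP antagonist GREM1, BHMT2, LPAR3, HSPA2 and PLBD1 were also higher in HOS. By size, 332 genes were higher and 351 lower in U2-OS in both states. With limma, 163 genes were higher and 191 lower at an adjusted p under 0.05, and each of the 20 genes named here passed, with adjusted p from 0.0117 to 0.0416 in limma. The limma count moved from 131 without the block to 1766 after quantile normalization.

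The list of TGF-beta and BMP targets, which also holds ligands and the receptor TGFBR1, was higher in U2-OS, with a median difference of 1.15. Of its members, 8 were higher and 1, GREM1, lower by size. With limma, 7 were called over all genes and 12 adjusted over the list alone. NOG differed by 2.70 and 2.94 and the ligand INHBA by 2.20 and 2.23. The list of matrix proteases also holds the protease inhibitors TIMP1, TIMP2 and TIMP3 and the receptor PLAUR. Its median difference was 0.84 over 12 genes at the level, with MMP2 at 3.17 and 2.55. Endoplasmic reticulum chaperones had a median difference of 0.34. Small nucleolar RNA genes were lower in U2-OS, with a median difference of -0.61, or -0.20 over all measured members. Each of these 4 lists stood apart without OGE and with it. Other lists stood apart over the mean of the states but in only 1 of them. Without OGE, histone genes differed by a median of 0.70, autophagy genes by 0.26 and ribosome biogenesis genes by -0.63, and with OGE these medians were 0.04, 0.12 and -0.22, within the range of random lists. With OGE, metallothionein genes differed by 1.05, immediate early genes by 0.57 and proteasome genes by -0.55, and without it these medians were 0.29, 0.22 and -0.22, within that range. Over all measured members, the histone difference over both states was 0.11 and no longer stood apart, and the immediate early one was 0.27.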

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

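The difference of list medians between the lines was chosen as a measure after the list results had been seen, and its percentiles among random lists describe these arrays and are not a test.

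The 12083 probe sets with no gene in the annotation used entered no comparison of genes or lists. Of these, 4154 were at the floor in both lines. In HOS, 258 were higher and 245 lower with OGE by size, and in U2-OS 390 and 347. In both lines, 67 were higher and 87 lower, and 28 were called in opposite directions. Among the 10811 genes at the floor in both lines, 201 were called in the same direction and 0 in opposite directions. Whether these probe sets are noisier was not tested. Among the 1754 probe sets with several symbols, 31 were higher and 10 lower in both lines.

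In 3 lists with medians of opposite sign in the lines, the median difference of the responses, taken gene by gene, also stood apart among random lists. Replication-dependent histone genes had medians of 0.04 in HOS and -0.48 in U2-OS, a difference of -0.52, and a gene-by-gene median difference of -0.43 at percentile 0.195, with H2BC14 at -1.17 and -1.76 and H2BC5 at 0.13 and -1.39. Their median in HOS was 0.00 after quantile normalization and -0.0035 after cyclic loess, so the sign in HOS did not hold. Metallothionein and zinc export genes had medians of -0.26 and 0.35, which stood apart in neither line, at percentiles 13.8 and 96.3, a difference of 0.61, and a gene-by-gene median difference of 0.71 at percentile 100, with the zinc exporter SLC30A1 at 0.26 and 1.02 and MT1X at -0.41 and 0.35. Over all measured members, the U2-OS median was also 0.35 and stood apart, at percentile 98.0. Proteasome genes had medians of 0.04 and -0.25, which stood apart in neither line, at percentiles 72.6 and 13.3, a difference of -0.29, and a gene-by-gene median difference of -0.32 at percentile 0.77, with PSMA4 at -0.71 and -1.25.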

How the results depend on the processing

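The noise added to undo rounding was chosen after the data were seen. All 219 alternatives tried for genes named by their change with OGE kept the call. They covered quantile normalization, cyclic loess and the mean of probe sets, with 73 changes each, for genes chosen for large changes. Such alternatives could change few calls. Only 769 of 18417 genes have more than 1 probe set, and RMA had already normalized the arrays. Other thresholds and floors, and the genes named between the lines, were not tried there. At 3-fold, several named genes would lose a call. In HOS these include HMOX1 with a change of 1.14, PLIN2 with 1.51, SKA2 with -1.22, ACADM with -1.15, TGFB2 with -1.57 and FSTL1 with -1.48. RCN2, with -1.58 in each line, and ANXA1, with -1.56 and -1.55, would lose their calls in both lines. Of all genes called in both lines, 14 higher and 5 lower were left at 3-fold. Of the alternatives for gene lists, 384 kept the call, 9 newly stood apart, 3 no longer did and 0 reversed. With a threshold of 1.5-fold, 1939 genes were called in HOS, 3296 in U2-OS, 944 in both lines in the same direction, 40 in opposite directions and 1774 between the lines. At 3-fold these were 48, 293, 19, 0 and 206, and these shifts follow from the threshold itself. Genes called in opposite directions numbered 2 with no floor and 1 after quantile normalization, and 445 genes differed between the lines with a floor at the 75th percentile. For OGE, limma called 1 gene with trend and robust moderation, 272 after quantile normalization and 0 in its other alternatives, cyclic loess and rounding noise included, with smallest adjusted p from 0.0165 to 0.761; the cause was not tested. Between the lines, limma called 1309 genes with trend and robust moderation, 131 without the block, 749 among genes at or above the median level, 1766 after quantile normalization, 1326 after cyclic loess and 1295 with rounding noise. The correlation of the responses was 0.442 over all genes, 0.652 at or above the 75th percentile and 0.535 as Spearman's rho. Leaving out a line or a treatment state leaves no residual degree of freedom, so limma gave no value there, and a pseudocount did not apply to log2 values. Signal near the array floor limits what can be said of low genes.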

Other observations

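The test of other short RNAs, and the tests of protein-coding and of noncoding genes that contain small nucleolar RNAs, were chosen after the result was seen, while the test of all such genes together was planned.

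Further lists stood apart in 1 line. In HOS, autophagy and lysosome genes had a median of 0.34, at percentile 99.9, against 0.21 at percentile 97.3 in U2-OS, with SQSTM1 higher by 2.15 and 1.63 and GABARAPL1 by 1.95 and 0.77. In U2-OS this list stood apart under each alternative, with medians from 0.21 to 0.30. Pro-apoptotic genes had a median of 0.24 in HOS and 0.21 in U2-OS, with PMAIP1 higher by 1.40 and 0.95. The median in HOS was 0.16 over all measured members and no longer stood apart. YAP and SRF targets had medians of -0.40 and -0.17, the second -0.11 after quantile normalization, with TPM1 at -1.41 and -2.46. Iron genes had medians of -0.58 and -0.30, the second -0.08 over all measured members, although FTL and HMOX1, the members called by size in both lines, were higher.

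In U2-OS, given first here, sterol synthesis genes had a median of -0.59 against -0.12 in HOS, with SC5D at -1.66 and -0.74. The TGF-beta and BMP list, of targets, ligands and a receptor, had -0.44 against -0.10 in HOS, where the sign turned to 0.03 over all measured members. Its member PMEPA1 had changes of -1.76 and -0.32, while the ligand BMP2 was higher by 1.86 and 0.26. NF-kB targets had 0.34 against 0.14, with TNFAIP3 higher by 2.67 and 0.43 and NFKBIA by 1.91 and 0.08. Ribosomal protein genes had 0.19 against 0.09, and 0.34 in U2-OS after cyclic loess. The random lists were not matched on gene span, and the 2284 genes of shortest span had medians of 0.17 in U2-OS and 0.11 in HOS. Ribosome biogenesis genes had 0.21 against 0.05, with NOP16 at 1.81 and -0.09; they had 0.34 in U2-OS after quantile normalization and over all measured members, which were the same 21 genes, the median was still 0.21 but its percentile was 97.1 against 97.7, since the genes drawn for the random lists differed.

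Heat shock genes stood apart in neither line, with medians of -0.11 in HOS and -0.40 in U2-OS, at percentiles 25.2 and 5.42, and the HOS median was 0.0012 after quantile normalization. Of their members, HSPB8 and DNAJB1 were higher by size in both lines and HSPA6 had changes of -0.28 and 3.30. The lists of interferon-stimulated genes, respiratory chain genes, osteoblast markers, aryl hydrocarbon receptor targets, cyclin-dependent kinase inhibitors, anti-apoptotic genes and matrix proteases had medians in HOS of 0.29, -0.08, -0.06, 0.24, 0.08, -0.05 and 0.18 and in U2-OS of 0.01, -0.02, 0.10, 0.25, 0.24, -0.18 and -0.02, and stood apart in neither line. The sign of the median turned under at least 1 alternative for the respiratory chain and anti-apoptotic lists in both lines, for the kinase inhibitors in HOS and for the interferon, osteoblast and protease lists in U2-OS. Over all measured members, the interferon list stood apart in HOS with a median of 0.18, at percentile 99.0, and the aryl hydrocarbon receptor list in U2-OS with 0.45, at percentile 98.97.

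Small nucleolar RNA genes were higher with OGE in both lines. Their median in HOS was still 0.4665 after cyclic loess, so a level trend left in the deposited values does not carry it. RMA had already brought the arrays to a common distribution, so an effect of RMA itself could not be tested and stays open. In the planned test, all 26 genes that contain such an RNA had a median of 0.18 in U2-OS, at percentile 97.995 among random lists. This median was over the bound of 0.1 set against their rise as the cause. Its upper 95% bootstrap bound of 0.28 lay under the 0.485 that their rise as the cause required. The 0.485 was set from all 72 small RNAs, while the 36 in these genes had a median of 0.705. A part played by these genes in U2-OS thus stays open. In HOS their median of -0.03 lay under the bound of 0.1, but its interval from -0.18 to 0.35 left HOS undecided. For the 30 of 72 small RNAs in protein-coding genes, a rise in the measured level of these hosts as the whole cause is argued against. These hosts had medians of -0.065 in HOS and 0.105 in U2-OS. The small RNA was above its host in 24 and 25 of 31 pairs, and the lower 95% bounds of the median gap were 0.24 and 0.31. These bounds resample hosts and include no spread between arrays. Transcription of the hosts was not measured, so it stays open, as does a partial contribution. The 4 noncoding hosts had medians of 0.51 in HOS and 1.78 in U2-OS, against 0.785 and 1.28 for their small RNAs, and the planned test on SNHG genes had 1 gene at the level, so a rise of this part of the hosts stays open in both lines. A higher yield of short RNAs may account for part of the pattern: other short RNA genes stood at percentile 96.98 in HOS and 100 in U2-OS, and the HOS value missed the limit set for standing apart by too little to decide.

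More genes were called in U2-OS than in HOS. Noisier U2-OS arrays stay open: the ratio of the spreads was 1.056 among the 8328 probe sets of lowest level and 1.35 among the 16651 of highest level, which met the bound set against noise, but noise is compressed near the array floor and no repeat array measures it at higher levels. Between-array scaling stays open. U2-OS had 2.836 times the calls of HOS after cyclic loess and 2.995 times after quantile normalization, against 2.83 as deposited. RMA had already brought the arrays to a common distribution, so a further normalization could change little. A larger response of the same genes may contribute, and its test is undecided. Genes called in HOS had a median ratio of 0.746 of the U2-OS change to the HOS change, which met the bound set against the explanation. That bound was wrong, because choosing genes by their change in one line lowers the ratio: genes called in U2-OS gave 0.375 in the reverse direction.

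Genes of longer span were lower with OGE. Spearman's rho across 9133 genes, which are not independent replicates, was -0.241 in HOS and -0.325 in U2-OS, and the median change went from 0.11 and 0.17 in the 2284 genes of shortest span to -0.13 and -0.28 in the 2283 of longest span. After cyclic loess rho was -0.249 in HOS and -0.336 in U2-OS, so a level trend left in the deposited values does not carry it. An effect of RMA itself could not be tested in this way and stays open. Without any list member, rho was -0.242 in HOS over the 8615 genes left. Most genes were kept, so this says only that list members alone do not carry the trend, and related genes outside the lists stay open. Reduced transcription of long genes is a candidate explanation that was not tested. The length of the transcripts was not used here, and the yield of long RNAs stays open, as does a difference between the lines.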
